A study of Mus musculus with 4 samples.

How the data were processed

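Splenic Treg cells of wild-type mice and of mice with floxed Eos and Foxp3-Cre were isolated with a CD4+CD25+ kit, fixed for 10 min in 1% formaldehyde and immunoprecipitated with 6 µg of antibody from a stated range of cell numbers, per the labels' protocols. The 4 libraries form 4 groups of 1 (wild-type and Eos knockout, each with anti-Eos and anti-Helios). The 2 knockout libraries were not analysed here. Cutadapt 4.4, BWA 0.7.1, Picard, SAMtools 1.17 and deepTools 3.5.1 are named per the submitters' processing notes, with the builds mm10 and GRCm38.p6. The peak caller, its settings and the control library of each list are not given in the sources used here.

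Each deposited list held 1 line per peak with the authors' values: the ratio (fold enrichment) over background, the -log10 p-value and -log10 q-value, an integer score and the offset of the summit from the peak start (another per-peak number). The deposited score was the whole part of 10 times the -log10 q for all 1106 and 469 peaks. Peaks were called separately for each library, so the lists were compared by overlap, and folds were used to describe and rank peaks within a list. The smallest -log10 q was 2.08 for anti-Eos and 2.24 for anti-Helios, so weaker places were not listed.

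The depth behind each peak was recovered from the deposited fold and p-value. A formula of the kind used by MACS, with fold as scaled fragments plus 1 over local background plus 1 and p as an upper Poisson tail, was solved for a whole number of fragments and a local background. It gave both deposited values for 100% of the peaks of each list within a relative tolerance of 0.0001. That this formula was used is an inference from the values. The scaling of the fragments was 1 for anti-Eos, whose control was scaled by 0.943, and 0.895 for anti-Helios. The recovered genome-wide background was 0.542 and 0.672 fragments. Fragment lengths of 115 and 120 bp were fitted to the steps of the local background, with 62.0% and 58.9% of the values on whole steps within 0.02 of a step. Together these put the anti-Helios library at 1.33 times the reads of the anti-Eos library (1.34 with the smallest peak width as fragment length), and its control at 1.13 times. Few fragments per peak mean that a fold of a single peak is imprecise, and the local background of a typical peak was 1 control fragment. Peaks are called high-background below where the local background exceeds 3 control fragments by more than 0.01.

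The gene table used here, of GRCm38.p6, has gene starts and ends but no strand, exons or transcripts, and no genome sequence was used here. Of its 49997 genes, 49939 lie on the chromosomes used, 21883 of them protein-coding. In place of transcription start sites, as the design had set, summits were assigned to the protein-coding gene with the nearest annotated end, either end, within 100 kb, and a summit within 1 kb of such an end was called near. A gene start and a gene end therefore could not be told apart, and exon, intron and UTR classes were not assigned. Expected shares were taken over the 2703 Mb between the first and last annotated gene of each chromosome, with gaps kept. Within 100 kb, 1047 anti-Eos and 453 anti-Helios summits were assigned.

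Overlap meant at least 1 bp in common. Chance overlap came from 1000 seeded placements of the anti-Helios peaks on the same chromosomes (one-sided). Median folds of shared and unshared peaks and correlations across pairs were tested with 100000 permutations (two-sided). Shares have 95% Wilson intervals, differences of shares Newcombe intervals, and ratios of observed to expected summits exact binomial (Clopper-Pearson) intervals. Near-end shares and chromosome shares were tested with two-sided exact binomial tests, and the antibodies were compared with two-sided Fisher's exact tests. Fisher's tests and Newcombe intervals between the lists treat them as independent, although overlapping peaks count in both. For each of 16 gene lists fixed before the data were examined, the number of assigned summits was tested against uniform placement (exact binomial, one-sided), with Benjamini-Hochberg adjustment over the 16 lists within each antibody and a threshold of 0.05. The lists were Treg core genes (37 genes, 5 of them also in another list), Ikaros family (5, 2 also in another), homing (25, 2), T cell receptor signalling (38), interleukin-2 and STAT5 axis (18, 3), effector T helper genes (30), T cell transcription factors (36), NuRD and corepressor subunits (24), markers of B cells (14), myeloid cells (16), CD8 and NK cells (11) and erythroid cells (11), liver genes (16), neuronal genes (16), ribosomal protein genes (84) and histone genes (67). All genes of these lists were found in the gene table.

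The rule for named items, fixed likewise, took the 15 peaks with the highest fold in each list, listed genes with summits in both lists, up to 20 further listed genes with the highest fold (ribosomal, histone and negative lists left out), the 10 shared pairs with the highest smaller fold, the 5 genes with the most summits per list, and Ikzf4, Ikzf2 and Foxp3. Some items that this rule or a test gave are not reported here. Members of a list that are named beside its count, without values, fall outside this rule. Alternatives fixed at the same time were a -log10 q of at least 5, a fold of at least the median of the list, a reciprocal overlap of at least 50%, summits within 100 bp, other distances to a gene end (5 kb for location, 10 and 500 kb for gene lists), ends of all gene types, placement within near-end and other classes, and Fisher's exact test over genes. Alternatives added after the data were seen left out high-background peaks, took as many of the top anti-Eos peaks as there are anti-Helios peaks, took only the anti-Helios peaks with a -log10 q of at least 5, used gene numbers for the chromosome shares, or used fragments in place of folds. The planned tests of 18 motifs and of 6-base words need a genome sequence and were not run.

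The scripts were tested on simulated data. Recovery of fragments returned the true counts for 100% of 290 and 274 simulated peaks, 187 of 187 planted overlaps were found, uniform summits gave any gene list call in 3 of 100 simulations, and 20 planted summits were called in 100 of 100. The real summits were not uniform, since many lay near gene ends. The rate of false gene list calls in these simulations therefore need not hold for the real lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.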

Results

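The study profiled 2 related zinc finger transcription factors of the Ikaros family in regulatory T cells (Treg cells), the CD4+CD25+ T cells that restrain immune responses. Eos is encoded by Ikzf4 and Helios by Ikzf2. Chromatin immunoprecipitation with sequencing (ChIP-seq), which recovers the DNA bound by a protein with an antibody against it, was carried out on mouse splenic cells that were wild-type or lacked Eos in cells expressing Foxp3-Cre. Of 4 libraries, 1 per antibody and genotype, the peak lists of the 2 wild-type libraries were used here. The anti-Eos list held 1106 peaks and the anti-Helios list 469. Peaks were narrow, with median widths of 175 bp for anti-Eos and 174 bp for anti-Helios. The median fold enrichment, which is the authors' own value per peak, was 7.31 for anti-Eos (interquartile range 6.09 to 9.19) and 7.66 for anti-Helios (6.30 to 9.31). Each fold is over a control library whose identity is not given in the sources used here, and the values imply that the 2 lists had different controls. If a control was the Eos knockout library of the same antibody, a peak marks more signal in wild-type than in knockout cells, and the number, folds and overlap of the anti-Helios peaks would not describe Helios binding as such. The fragment count recovered at the summit had a median of 14 for anti-Eos peaks (range 7 to 106) and 18 for anti-Helios peaks (range 9 to 124), so most peaks rested on few fragments. With 1 library per group there was no replicate error, and every test below describes these 2 libraries, alone or against each other, not the proteins or the genotypes. Intervals cover counting error only. Coordinates are those of GRCm38 (mm10).

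The highest anti-Eos peak lay at an end of Brpf1, which encodes a subunit of MOZ and MORF histone acetyltransferase complexes (chromosome 6, 113306445 to 113306973, fold 35.7). The next lay inside the T cell receptor beta locus (chromosome 6, 41554294 to 41554886, fold 33.7), with its summit 6.32 kb beyond the end of the constant gene Trbc2, on the side where the enhancer of that locus is known to lie. It was followed by a peak within Tiam1, a guanine nucleotide exchange factor for Rac (chromosome 16, 89904931 to 89905739, fold 27.9, 106 fragments). Peaks close to ends of Phf23 (25.1), Rps19 (24.4), Scaf8 (23.0), Vrk1 (22.1) and Socs1 (21.9), a feedback inhibitor of cytokine signalling, came next together with peaks within Nadk (22.7) and Znrf3 (22.6). The remaining 5 of the 15 highest were at Snx29, Ints9, Chmp5, Picalm and Flt3l, with folds of 20.1 to 21.6. All 15 overlapped an anti-Helios peak, and 10 of the 15 had their summit within 1 kb of an end of a protein-coding gene.

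The anti-Helios list was led by a peak within Arih1, an E3 ubiquitin ligase (chromosome 9, 59486648 to 59487002, fold 23.3). Peaks at Socs1 (chromosome 16, 10785045 to 10785591, fold 20.5), the heat shock gene Hspa1b (18.8), the cytokine gene Flt3l (18.6), Rps19 (17.5) and the actin nucleation gene Actr3 (17.0) followed. The same interval beyond Trbc2 ranked seventh (chromosome 6, 41554372 to 41554578, fold 16.8). The other 8 of the 15 highest lay at Izumo4, Shprh, Ldb1, Ddx20, Btbd19, Phf23, Il6ra and Cox18, with folds of 14.9 to 16.0. Of these 15 peaks, 14 overlapped an anti-Eos peak, the exception being the peak within Btbd19 (fold 15.2).

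The first comparison asked how far the peaks of the 2 antibodies fell at the same places in the same kind of cell. Overlap by at least 1 bp was found for 309 of 469 anti-Helios peaks (65.9%, 95% Wilson interval 61.5 to 70.0%) and for 309 of 1106 anti-Eos peaks (27.9%, 25.4 to 30.7%). The shared places with the highest smaller fold of the pair were at Socs1 (21.9 with anti-Eos, 20.5 with anti-Helios), Flt3l (20.1 and 18.6), Rps19 (24.4 and 17.5), the T cell receptor beta locus (33.7 and 16.8) and Arih1 (16.6 and 23.3). Phf23, Izumo4, Cdiptos, Tiam1 and Wdr5 completed the first 10. The place named for Wdr5 lay outside protein-coding genes, 3706 bp from its end and within 1 kb of the small nuclear RNA gene Gm25541. Random placement of the anti-Helios peaks on their own chromosomes gave a mean of 0.09 overlapping peaks and at most 2 over 1000 placements, with a one-sided permutation p of 0.000999, the smallest that this number of placements can give. Placement that kept each summit's class, near a gene end or not, gave a mean of 0.674. Narrow peaks placed in these ways rarely meet. The test therefore cannot tell joint occupancy by the factors from places that any antibody would recover from these cells. The lists also held 160 anti-Helios and 797 anti-Eos peaks without a partner.

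Sharing was more frequent among the peaks with the highest significance. Of the 118 anti-Helios peaks with the highest -log10 q, 91.5% were shared (Wilson interval 85.1 to 95.3%), and of the 117 with the lowest, 47.0% (38.2 to 56.0%). The corresponding shares were 55.2% (49.3 to 61.0%) for the 277 highest and 13.8% (10.2 to 18.3%) for the 276 lowest anti-Eos peaks. Shared anti-Eos peaks had a median fold of 8.75 against 7.07 for unshared ones (two-sided permutation p = 2e-05, the smallest that the resampling can give), and shared anti-Helios peaks 7.85 against 7.02 (permutation p = 2e-04). Across the 310 overlapping pairs the log2 folds of the 2 lists had a Pearson correlation of 0.277 (permutation p = 1e-05, the smallest that the resampling can give) and a Spearman correlation of 0.239 (permutation p = 3e-05). Without the 2 pairs farthest from the median anti-Eos fold these were 0.257 and 0.228. These correlations run across peaks, which are not independent replicates.

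**Figure D1:**
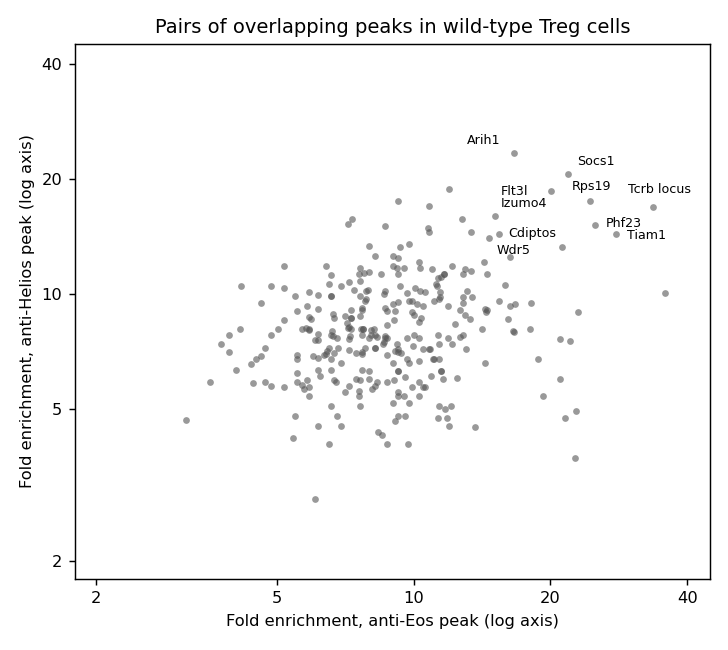
Fold enrichment of the anti-Eos peak (horizontal, log axis) against that of the anti-Helios peak (vertical, log axis) for the 310 pairs of overlapping peaks in wild-type Treg cells, 1 point per pair. The labelled points are the 10 pairs with the highest smaller fold, from Wdr5 (14.7 and 13.99) to Socs1 (21.9 and 20.5).

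**Figure D2:**
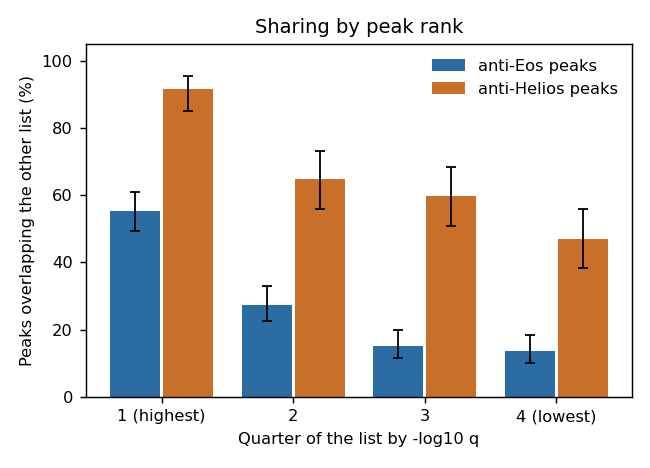
Percentage of peaks that overlap the other list, for each list split into 4 parts of nearly equal size by -log10 q, with 95% Wilson intervals as error bars. The share falls from 91.5% to 47.0% for anti-Helios peaks (orange) and from 55.2% to 13.8% for anti-Eos peaks (blue).

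The second comparison placed the summits relative to genes. Anti-Helios summits lay within 1 kb of an annotated end of a protein-coding gene in 239 of 469 cases (50.96%, Wilson interval 46.4 to 55.5%) and anti-Eos summits in 437 of 1106 cases (39.5%, 36.7 to 42.4%), against 2.93% of the annotated span of the genome. Examples in both lists were Zap70, Lat, Cd3d, Itgal and Junb. Summits elsewhere inside a gene made up 33.9% of anti-Eos and 29.2% of anti-Helios summits (36.5% of the span), among them those within Lef1, Prkcq, Ptprc and Il2rb. Summits outside genes made up 26.6% and 19.8% (60.5% of the span). The near-end share was 11.4 percentage points higher in the anti-Helios list (Newcombe interval 6.08 to 16.8, Fisher's exact test, two-sided p = 2.96e-05). Set against only the 469 anti-Eos peaks with the highest -log10 q, of which 45.4% were near an end, the difference was 5.54 points (interval -0.848 to 11.9, Fisher's exact p = 0.102), a comparison chosen after the data were seen. With a -log10 q of at least 5 in both lists it was 9.62 points (3.43 to 15.7, Fisher's exact p = 0.00272). Anti-Eos peaks shared with Helios were near a gene end more often than unshared ones (48.9% against 35.9%, Fisher's exact p = 9.11e-05). For anti-Helios peaks these shares were 48.9% and 55.0% (Fisher's exact p = 0.242). Of the 309 shared peaks, 151 were near an end in each list, so the lists differed only in their unshared peaks. The tests and intervals between the lists count the shared places in both and treat the lists as independent.

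The third comparison asked which of the fixed groups of genes held more summits than random placement gives. Random placement takes no account of which genes are active in T cells. A list that passes therefore cannot tell targeting by the factors from places that any antibody would recover from these cells. T cell receptor signalling genes held the most summits, with the smallest p, in both lists. They had 24 anti-Eos summits at 18 of 38 genes against 1.65 expected (14.5-fold, exact interval 9.33 to 21.5, adjusted p = 7.36e-19) and 11 anti-Helios summits at 11 genes against 0.701 expected (15.7-fold, 7.87 to 27.8, adjusted p = 3.82e-09). Both calls stayed when placement kept the near-end share of the summits (adjusted exact p of 4.58e-18 for anti-Eos and 1.14e-08 for anti-Helios). Genes with summits of both antibodies in this group included Zap70, a kinase that acts close to the receptor, the adaptor gene Lat, the receptor chain gene Cd3d, the phosphatase gene Ptprc, Prkcq, and the diacylglycerol kinase genes Dgka and Dgkz. At Dgkz no anti-Eos peak overlapped the anti-Helios peak. At Zap70 the folds were 13.3 with anti-Eos and 8.60 with anti-Helios, 50 and 54 bp from a gene end. Both antibodies also gave a peak between Dgka and Pym1, assigned to Dgka as the nearer (1286 and 1290 bp from its end, folds 13.4 and 11.4). Pym1 starts at 128747879, against summits at 128746370 and 128746374. An anti-Eos peak assigned to Cd28 (12.3, 3833 bp from an end) had no overlapping anti-Helios peak. The same held for 2 assigned to Cd69 (8.25 and 9.09, at 34260 and 9221 bp).

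Genes of the interleukin-2 and STAT5 axis, on which Treg cells depend, held 13 anti-Eos summits at 8 of 18 genes (26.4-fold, exact interval 14.1 to 45.03, adjusted p = 7.48e-14) and 4 anti-Helios summits at 4 genes (19.2-fold, 5.24 to 48.8, adjusted p = 0.000429). The 4 genes with summits of both antibodies were Il2rb, which encodes the receptor beta chain (10.3 and 12.1 at the shared peak within the gene), and the feedback inhibitor genes Socs1, Socs3 and Cish. At Socs3 no anti-Eos peak overlapped the anti-Helios peak. The shared peak assigned to Cish lay outside the gene, 10309 and 10204 bp from an end, with folds of 5.54 and 6.22. Il2ra, Il4ra, Mcl1 and Jak1 (10.4, 26897 bp from an end) had anti-Eos summits.

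T cell transcription factor genes held 14 anti-Eos summits at 10 of 36 genes (5.94-fold, exact interval 3.25 to 9.92, adjusted p = 7.95e-07) and 7 anti-Helios summits at 6 genes (7.003-fold, 2.83 to 14.3, adjusted p = 0.000429). Lef1, a factor of naive T cells, carried 3 anti-Eos peaks (10.0, 8.23 and 13.0) and 2 anti-Helios peaks (7.79 and 7.21) inside the gene. Bcl11b, Ets1, Fos and Junb also had summits of both antibodies, at Bcl11b with folds of 4.16 and 8.10. The peaks assigned to Fos lay outside genes, 18759 bp (anti-Eos) and 8717 bp (anti-Helios) from an end, and did not overlap. Tcf7, Runx1, Notch1, Relb and Tox had anti-Eos summits, and Jund an anti-Helios summit.

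Treg core genes held 12 anti-Eos summits at 9 of 37 genes (8.64-fold, exact interval 4.48 to 15.04, adjusted p = 1.52e-07). The 3 anti-Helios summits in this group did not pass the adjustment (5.10-fold, 1.05 to 14.8, exact binomial test, adjusted p = 0.0585), although they passed narrowly without high-background peaks (adjusted exact p = 0.0499), as did 2 summits with assignment within 10 kb (adjusted exact p = 0.0342). The 3 summits were assigned to Capg, to Izumo1r, which encodes a folate receptor of Treg cells, and to Tnfrsf18, which encodes GITR. That assigned to Izumo1r lay 22860 bp from an end. The shared peak assigned to Tnfrsf18, 4038 and 3883 bp from an end, had folds of 8.65 and 7.66, and that within Capg 10.3 and 5.87. These Tnfrsf18 summits lay within 1 kb of the small nuclear RNA gene Gm25982. Icos, Il2ra, Nt5e, Tnfrsf1b, Ikzf2 and Ikzf4 had anti-Eos summits.

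Homing genes passed in both lists, with 5 anti-Eos summits at Gpr183, Itgal, Klf2 and S1pr1 (5.90-fold, exact test, adjusted p = 0.00411) and 3 anti-Helios summits at Itgal and S1pr1 (8.35-fold, adjusted p = 0.0236). With a -log10 q of at least 5 neither homing call was kept (2 and 1 summits, adjusted exact p of 0.211 and 0.547), and 0 summits lay at these genes among the 469 anti-Eos peaks with the highest -log10 q. The anti-Helios homing call was also lost under Fisher's exact test over genes (adjusted p = 0.263). Effector T helper genes passed for anti-Eos, with 6 summits at Bcl6, Gata3, Il6ra, Pdcd1, Stat4 and Tnf (6.13-fold, exact test, adjusted p = 0.00141). Anti-Helios had 2 in this group, at Il6ra (15.1) and Pdcd1 (10.1; adjusted exact p = 0.150), and passed with assignment within 10 kb (2 summits, adjusted exact p = 0.0246) and within 500 kb (4 summits, adjusted exact p = 0.0266). Of the 5 Ikaros family genes, Ikzf1, Ikzf2, Ikzf3 and Ikzf4 held 1 anti-Eos summit each (16.2-fold, exact test, adjusted p = 0.000407) and no anti-Helios summit. Ribosomal protein genes passed with 5 anti-Eos (5.00-fold, adjusted exact p = 0.00726) and 3 anti-Helios summits (7.08-fold, adjusted exact p = 0.0295). Histone genes passed with 2 anti-Eos summits (8.53-fold, adjusted exact p = 0.0418). The ribosomal and histone calls ended when placement kept the near-end share of the summits (adjusted exact p of 0.133 and 0.390 for anti-Eos, and 0.243 for the ribosomal genes with anti-Helios).

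Genes of the NuRD and other corepressor complexes held 2 anti-Eos summits, at Chd3 (9.78) and Sin3a (9.81), and 1 anti-Helios summit, at Ncor1 (exact test, adjusted p of 0.317 and 0.521). B cell, CD8 and NK cell and erythroid markers, and the liver and neuronal genes taken as negative lists, held 0 summits in either list. With 3 counts taken as the upper limit for a count of 0, these lists could hold up to 0.271% of anti-Eos and 0.640% of anti-Helios summits. Less than 1 summit was expected for each of these lists. Myeloid markers held 0 anti-Eos summits and 1 anti-Helios summit, assigned to Cebpb from 84848 bp away (adjusted exact p = 0.313). In all, 9 of 16 lists passed for anti-Eos and 5 of 16 for anti-Helios. The share of summits differed between the antibodies for 0 of 16 lists (Fisher's exact test, smallest unadjusted p = 0.298, all adjusted p = 1).

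**Figure D3:**
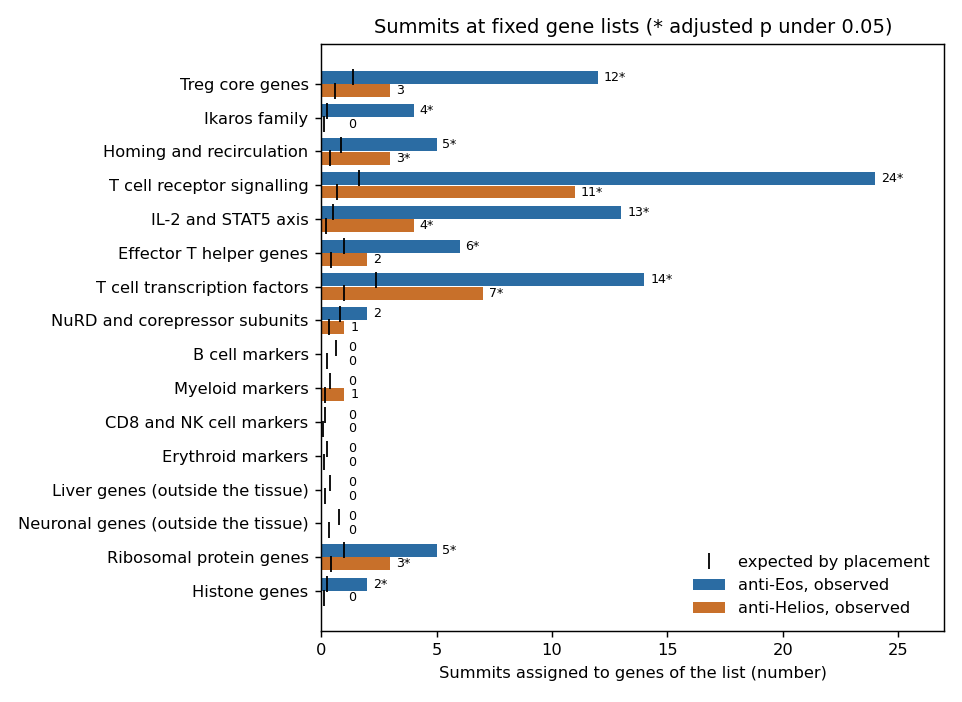
Number of summits assigned to the genes of each fixed list, for anti-Eos (blue) and anti-Helios (orange), with black ticks at the number expected by random placement. T cell receptor signalling genes hold 24 and 11 summits against 1.65 and 0.701 expected, while the B cell, liver and neuronal lists hold 0.

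The loci of the targeted and driver genes were then examined. Within Ikzf4 (chromosome 10, 128630839 to 128669671) lay 1 anti-Eos peak (128637012 to 128637261, fold 9.09, 17 fragments over a local background of 1.04 control fragments) and no anti-Helios peak. If the knockout library was the control, a deleted floxed stretch of Ikzf4 could leave a peak there without binding. This was not tested, and the same summit counts in the Ikaros family and Treg core lists. Beyond 1 end of Ikzf4, both antibodies gave a peak next to the ribosomal protein gene Rps26, 4.01 kb from Ikzf4 with anti-Eos (12.3) and 4.02 kb with anti-Helios (8.33). Ikzf2 carried an anti-Eos peak 168 bp from an end (chromosome 1, 69687092 to 69687266, fold 4.50, 12 fragments over 2 control fragments), and no anti-Helios peak lay within 100 kb. Another anti-Eos peak lay 81.5 kb from Ikzf2 (fold 6.24). No peak fell within Foxp3. The nearest, an anti-Eos peak within Ppp1r3f, lay 8.73 kb away (chromosome X, 7570905 to 7571037, fold 5.55, 8 fragments).

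**Figure D4:**
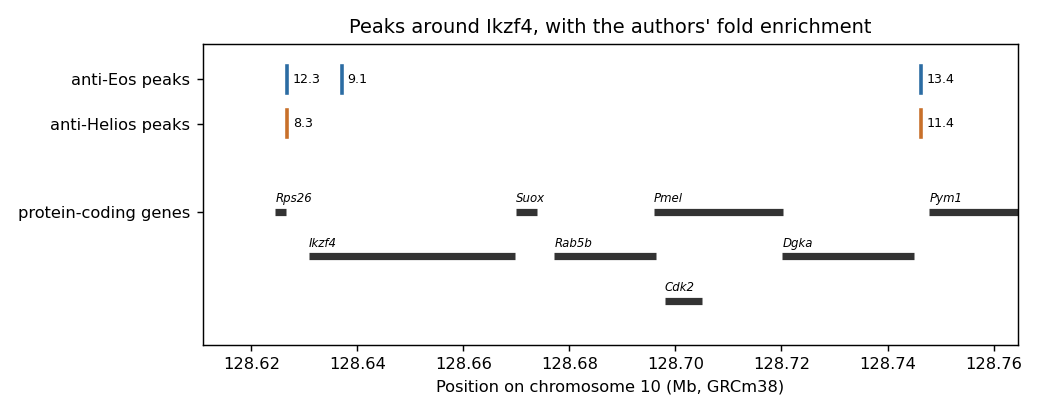
Map of the Ikzf4 region on chromosome 10 (GRCm38), with anti-Eos peaks (blue), anti-Helios peaks (orange) and protein-coding genes (black bars), drawn to scale in Mb except that peaks are lines of fixed width. The peak within Ikzf4 (fold 9.1) is anti-Eos only, while the peaks at Rps26 (12.3 and 8.3) and beyond Dgka (13.4 and 11.4) occur in both lists.

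Some genes carried several summits. Zfp36l2, which encodes an RNA-binding protein that promotes mRNA decay, had 6 anti-Eos and 3 anti-Helios summits, and the potassium channel gene Kcnn4 had 4 and 2. Septin9 had 5 anti-Eos summits and Emsy 4. Gm34296 had 3 anti-Helios summits, and Arid1a, which encodes a subunit of the BAF chromatin remodelling complex, had 2. Sfi1 had 4 anti-Eos and 8 anti-Helios summits, over local backgrounds of up to 33.2 and 37.0 control fragments. By chromosome, chromosome 11 held 2.37 times its expected number of anti-Eos peaks (118 peaks, exact binomial test, adjusted p = 4.45e-16) and 2.60 times that of anti-Helios peaks (55 peaks, adjusted p = 3.71e-09). Sfi1 lies on chromosome 11, so its 4 and 8 summits are among these peaks, and the test counts each as independent. The chromosome tests were not repeated without high-background peaks. Chromosome X held 18 anti-Eos peaks, 0.258 times the expected number (exact test, adjusted p = 5.88e-13), and 3 anti-Helios peaks, 0.101 times (adjusted p = 5.25e-09). Against the number of protein-coding genes, an expectation chosen after the data were seen, the ratios were 1.45 and 1.59 for chromosome 11 (adjusted exact p of 0.000462 and 0.00747) and 0.369 and 0.145 for chromosome X (adjusted exact p of 1.06e-05 and 5.36e-05). The X shares of the 2 lists were not shown to differ (Fisher's exact p = 0.151). Both expectations treat chromosome X as present in the same copy number as the autosomes, and the sex of the mice was not considered. In all, 10 chromosomes departed from their expected share for anti-Eos and 4 for anti-Helios, the latter 2 when the expectation was taken from gene numbers.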

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

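The tests of read depth and control depth and the limit to the top anti-Eos peaks were chosen only after the result was seen, as was the repeat that counts peaks at exactly 3 control fragments.

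The near-end share differed between the lists, 50.96% of anti-Helios against 39.5% of anti-Eos summits, a difference of 11.4 percentage points. High-background places do not account for it, since without them the difference was 12.4 points (Fisher's exact p = 1.11e-05). Weaker peaks in the longer anti-Eos list are a candidate explanation, and with the 469 anti-Eos peaks of highest -log10 q the difference was 5.54 points (interval -0.848 to 11.9, Fisher's exact p = 0.102). With a -log10 q of at least 5 in both lists, however, it was 9.62 points (3.43 to 15.7, Fisher's exact p = 0.00272), so these 2 ways of removing weak peaks do not settle the question. Weaker anti-Eos peaks and a difference between the factors cannot be told apart here, since each antibody has 1 library. Shared peaks also count in both lists, which these tests treat as independent.

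The anti-Helios list held 469 peaks against 1106 for anti-Eos, 2.36 times fewer. Fewer reads in the anti-Helios library would be needed for a depth effect, but the recovered backgrounds put it at 1.33 times the reads of the anti-Eos library. Its library-to-control ratio was 1.18 times that of the anti-Eos library, which argues against a relatively larger control. The yield of each antibody, a control library that itself holds bound fragments, as the knockout anti-Helios library would if it served as control, and a true difference in the number of bound places remain open and untested.

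High-background places drew attention because the control library itself held fragments there: 25 anti-Eos and 28 anti-Helios peaks had a local background over 3 control fragments. Examples lay in and beside Sfi1, which had the highest (up to 33.2 and 37.0 control fragments), at C130026I21Rik (12, an unshared anti-Eos peak), beside Scaf8 at the pseudogene Pisd-ps2 (11 and 24) and within Pisd (9 and 8). The median folds over all such peaks were 4.61 and 4.57 against 7.38 and 7.73 for the others. Single peaks went higher, such as an anti-Helios peak beside Sfi1 (8.61). Local background is in the denominator of the fold, so a lower median follows in part from the selection. Copies of a sequence collapsed in the assembly could give peaks shared between the lists, and 68.0% of such anti-Eos peaks were shared against 27.01% of the others (Fisher's exact p = 2.92e-05), while for anti-Helios peaks these shares were 64.3% and 66.0% (Fisher's exact p = 0.840). Counting peaks at exactly 3 control fragments as well gave 77.4% and 64.4% for anti-Helios (Fisher's exact p = 0.0659). With 28 such peaks and a high share among the others, these shares cannot tell collapsed copies from true binding for the anti-Helios peaks. The anti-Eos shares cannot tell either, since such peaks need more fragments to be listed and the shares were not matched for that. Of the Sfi1 summits, 1 of 4 with anti-Eos and 1 of 8 with anti-Helios were shared. The high background was not always common to both lists. At the shared peaks at Nadk, Znrf3 and Brpf1 it was 1.04, 1.00 and 0.692 control fragments for anti-Eos against 5.00, 6.00 and 4.00 for anti-Helios. In the other direction, at Ddx20 and Ldb1 it was 5.00 and 4.00 for anti-Eos against 1.00 for anti-Helios at each. At Pisd-ps2 and within Pisd it exceeded 3 in both.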

How the results depend on the processing

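The settings that left out high-background peaks, limited the anti-Eos list to its top peaks, limited only the anti-Helios list by -log10 q, used gene numbers for chromosomes, or changed the pairs or measure of the correlation were chosen only after the data were seen. Of 51 alternative values for the comparisons themselves, 46 kept their direction and side of the threshold, or stayed within 1.5 times for a count. The shared number of anti-Helios peaks ranged from 231 to 309 over all settings, each with the smallest permutation p. A fold of at least the median left 553 anti-Eos and 237 anti-Helios peaks by construction. The near-end difference fell to 5.54 points with as many top anti-Eos as anti-Helios peaks, by a setting that removes the weaker anti-Eos peaks. The number of gene lists passing for anti-Helios was 3 under Fisher's exact test over genes, which counts a gene once (T cell receptor signalling, interleukin-2 and STAT5 axis, and T cell transcription factors), and chromosomes off their share for anti-Helios were 2 when expected from gene numbers; the cause was not tested. Among 208 alternative values for single gene lists, 192 were the same, 10 no longer passed, 4 newly passed (Treg core genes and effector T helper genes with anti-Helios, under 2 settings each) and 2 turned: the homing list with top anti-Eos peaks (0 summits) and the histone list under Fisher's exact test over genes (2 genes, fewer than expected); the cause was not tested. No paired analysis was possible because each group has 1 library, and leaving out replicates was not possible either. Alternatives of the motif and 6-base word tests were not run, since no genome sequence was used. Few fragments per peak (medians of 14 and 18) limit the precision of each fold.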

Other observations

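The tests of snRNA and other gene types and the comparison of fragments with folds, and the choice of the T cell receptor alpha interval and of the genes named here, were made only after the data were seen.

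Both antibodies also gave peaks beyond the T cell receptor alpha constant gene Trac, in the interval before Dad1 that is known to hold the enhancer and the locus control region of Tcra. A first pair of peaks had summits 3.27 kb (anti-Eos, chromosome 14, 54227324 to 54227670, fold 6.24) and 3.36 kb (anti-Helios, 54227453 to 54227659, fold 6.09) beyond Trac. The second had both summits 9.25 kb beyond Trac and 2.04 kb before Dad1 (anti-Eos, 54233260 to 54233748, fold 19.2; anti-Helios, 54233289 to 54233549, fold 5.397). With the peaks beyond Trbc2, both antibodies had peaks past a constant gene at both receptor loci. Of 884 genes with an assigned anti-Eos summit and 419 with an anti-Helios summit, 302 were the same.

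Among the 310 shared pairs, 32 had folds at least 2 times apart, and in 27 of these (84.4%) the fragment numbers were within 1.5 times of each other, as they were in 233 of the 278 other pairs (83.8%). Brpf1 had a fold of 35.7 with anti-Eos and 10.0 with anti-Helios, from 58 and 55 fragments over local backgrounds of 0.692 and 4.00 control fragments. Vrk1 had 22.1 and 7.54 from 42 and 41 fragments over 1.00 and 4.00, and Chmp5 21.0 and 5.98 from 36 and 39 fragments over 0.808 and 5.00. In the other direction, Ldb1 had 7.33 and 15.7 from 34 fragments in each, over 4.00 and 1.00. Tiam1 is different, with 27.9 and 14.3 from 106 and 63 fragments over 3 control fragments in each list. Across the 310 shared pairs the fragments had a Pearson correlation of 0.723 on the log2 scale and a Spearman correlation of 0.656 (permutation p = 1e-05 for each, the smallest possible), against 0.277 and 0.239 for the folds. Without pairs of high background these were 0.660 and 0.612 for fragments and 0.337 and 0.273 for folds, over 279 pairs.

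A hypothesis that summits lie at small nuclear RNA (snRNA) genes more often than by placement was tested within 500 bp of 1004 annotated genes. Of the anti-Eos summits, 11 lay there against 0.457 expected (24.1-fold, exact binomial p = 2.86e-12), and of the anti-Helios summits 4 against 0.194 expected (20.6-fold, exact p = 4.98e-05). Among summits over 1 kb from a protein-coding gene end these were 8 (28.9-fold, exact p = 6.37e-10) and 3 (31.6-fold, exact p = 0.000132). Other gene types were tried too. For anti-Eos the ratio was 31.5-fold at tRNA genes (5 summits, exact p = 7.29e-07), 10.3-fold at miRNA genes (5 summits, exact p = 0.000147) and 1.796-fold at lncRNA genes (171 summits, exact p = 1.68e-13), against 1.68-fold at snoRNA genes (1 summit, exact p = 0.448) and 0.530-fold at pseudogenes (8 summits, exact p = 0.0684). For anti-Helios it was 29.7-fold at tRNA genes (2 summits, exact p = 0.00216), 4.87-fold at miRNA genes (1 summit, exact p = 0.186) and 1.68-fold at lncRNA genes (68 summits, exact p = 2.38e-05). Anti-Helios had 0 summits at snoRNA genes and 6 at pseudogenes (0.938-fold). Over 1 kb from a protein-coding gene end, tRNA genes had 1 anti-Eos summit (10.4-fold, exact p = 0.0915) and 0 anti-Helios summits (exact p = 1), and miRNA genes 3 (10.2-fold, exact p = 0.00335) and 1 (9.93-fold, exact p = 0.0958). The lncRNA ratios there were 2.07 for anti-Eos (exact p = 5.41e-14) and 2.17 for anti-Helios (exact p = 1.41e-06). These p-values are not adjusted for the gene types tried. snRNA genes occur in many similar copies, and whether reads were placed uniquely is not given in the sources used here.

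A further hypothesis was that single families of gene symbols hold more near-end summits than other genes, tested over 143 families of at least 15 genes per list. In the anti-Eos list 2 families passed Fisher's exact test. The protein phosphatase family Ppp had 8 of 77 genes with a summit against 1.45 expected (Ppp1ca, Ppp1cb, Ppp1r11, Ppp1r12a, Ppp1r8, Ppp1r9b, Ppp2ca and Ppp2r1a; exact test, adjusted p = 0.0140). In the anti-Helios list 0 passed, with 5 Ppp genes against 0.827 expected (exact test, adjusted p = 0.103) and the Integrator genes Ints3, Ints4 and Ints9 against 0.161 expected (exact test, adjusted p = 0.0723). The difference between the lists was not tested.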
